A study of Homo sapiens with 4 samples.

How the data were processed

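The data are RNA-seq gene counts from SW1990 cells, an established human pancreatic ductal adenocarcinoma line, after 24 h with vehicle or with 10 µM gomisin G, a lignan of Schisandra fruits. There were 2 libraries per group and 4 in all. Per the labels, total RNA was depleted of ribosomal RNA before library construction. Such depletion keeps RNAs without poly(A) tails, such as 7SK, 7SL and most histone transcripts, but these were scarce here. Protein-coding genes, those of mitochondria included, held 97.4 to 97.7% of counts. Nuclear ribosomal RNA, 7SK and 7SL genes together held 0.00905 to 0.0246%, and the listed replication-dependent histone genes 0.0035 to 0.00797%. These shares go against the label as the only selection step, and poly(A) selection is not excluded. Reads left uncounted for matching several places would also lower them. The deposited values are raw counts per gene, which the authors made from their reads and which carry no normalization. The submitters' processing notes name fastp, HISAT2 and featureCounts, tools for trimming, aligning and counting reads, and the genome build hg38, with no versions or settings. Whether the counting used the strand of the reads is not given in the sources used here, so reads from a gene and from its antisense partner cannot be told apart. Whether reads that match several places were counted is likewise not given in the sources used here, so values of genes with near-identical copies are uncertain.

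The counts of the whole-series table and of the 4 sample tables were compared, and 0 values differed. All 58735 gene identifiers, and the coordinates of all 58735, were the same as in GENCODE release 29 on GRCh38, and 58207 identifiers matched a table of current gene symbols. Where a current symbol differs from that of the files, as for CCN1 (CYR61 in the files) and CCN2 (CTGF in the files), the current one is used. Total counts were 14580848 and 14901526 in the vehicle libraries and 15034663 and 15245770 in the gomisin G libraries. At these depths 3 counts equal 0.197 to 0.206 CPM (counts scaled to library size), which is the floor for a gene with a count of 0. Intervals and floors of this kind cover counting error only. A chi-square comparison of the counts of each pair of libraries, over genes with at least 20 counts, gave 6.98 per gene for the vehicle pair and 37.2 per gene for the gomisin G pair. Neither pair was a single library deposited more than once by this measure. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

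Genes were compared with edgeR 4.0.16 in R 4.3.3. The steps were the default expression filter by group, TMM factors, and the robust quasi-likelihood F test with the newer (not the legacy) estimation of dispersion. The design held treatment alone and left 2 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p below 0.05 over the 15721 tested genes are called. Log2 changes are gomisin G minus vehicle, with their standard error (SE), and CPM values use the TMM factors. The test was run first on simulated counts for the same 15721 genes. It called 12% of genes changed 1.5-fold, 54% of those changed 2-fold, 90% of those changed 4-fold and 94% of those changed 8-fold, with 125 true and 3 false calls, and made 0 calls where nothing was changed. The simulated genes were independent, with a dispersion set by expression level alone and equal in both groups, and with no length trend. In the real libraries the gomisin G pair differed more than the vehicle pair, so these rates may not hold for them.

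The 32 gene lists were fixed before the data were examined, as were the tests, the alternatives (except those named here as later ones) and the rule for named genes. Each list was compared with all other tested genes by camera in limma 3.58.1 on voom log2 CPM, with the inter-gene correlation preset at 0.01 and Benjamini-Hochberg adjustment over the 32 lists. On simulated counts camera called 5 of 5 lists shifted by 1 on the log2 scale and 0 of 15 unshifted lists. Genes were simulated independently and lists drawn at random. That run therefore does not test false calls for lists whose genes vary together, or smaller shifts. Each list was also tested by camera with an estimated correlation, which called 0 lists (3 had an unadjusted p below 0.05), and by fry, which asks whether a list's genes move on balance in 1 direction and called 2. The adjusted p-values of the list tests are from camera with the preset correlation unless another test is named.

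The named genes are of 3 kinds. The first are YAP1, WWTR1, CCN1, CCN2, ANKRD1 and AMOTL2, taken whatever their values because the series is about the Hippo-YAP pathway. The second are the 10 largest increases and the 10 largest decreases among called protein-coding genes with a mean log2 CPM of at least 1 and with both gomisin G libraries beyond both vehicle libraries. The third are up to 4 members with the lowest p from each called list and up to 2 from each other list. Any other gene that is named was chosen after its values were seen and is introduced as such. Some genes that the rule names are not reported here.

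The alternatives were median-ratio (RLE) and upper-quartile factors, removal of mitochondrial, ribosomal RNA, 7SK and 7SL genes, no expression filter, a minimum of 50 counts in 2 samples, a non-robust fit, the legacy fit, limma voom, DESeq2 1.42.0, the replicate number as a block, and each library left out in turn. After the data were seen, 2 more were added. These fitted in each library a smooth trend with exon length, or with exon length and transcript GC content, on genes with a mean log2 CPM above 4. The trend was then removed from all tested genes. No sample was left out of the main tests.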

Results

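RNA-seq counts were analysed from SW1990 pancreatic cancer cells treated for 24 h with vehicle (2 libraries) or with 10 µM gomisin G (2 libraries). Total counts per library ranged from 14580848 to 15245770. Of all annotated genes, 30575 had at least 1 count and 15721 passed the expression filter. The series names the Hippo-YAP pathway, in which the LATS kinases restrain the transcriptional coactivators YAP (gene YAP1) and TAZ (gene WWTR1). The comparison therefore asks which transcripts, those of this pathway among them, differ between gomisin G and vehicle.

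Transcripts of the best-known YAP/TAZ target genes fell with gomisin G. CCN1, a secreted matricellular protein gene, fell from 38.9 ± 1.21 to 4.62 ± 0.201 CPM (mean ± SD, n = 2 libraries each). AMOTL2, which encodes an angiomotin that binds YAP, fell from 153.7 ± 10.4 to 21.6 ± 4.13 CPM, and CCN2 fell from 3.88 ± 0.606 to 0.554 ± 0.198 CPM. The log2 changes were -3.07 (SE 0.19, adjusted p = 0.00147) for CCN1, -2.83 (SE 0.19, adjusted p = 0.00163) for AMOTL2 and -2.77 (SE 0.42, adjusted p = 0.0253) for CCN2. CCN1 lies on chromosome 1 at 85580761 to 85583962, AMOTL2 on chromosome 3 at 134355874 to 134375479 and CCN2 on chromosome 6 at 131948176 to 131951373 (GRCh38). The target ANKRD1 had 22 counts over both vehicle libraries and 4 over both gomisin G libraries, a vehicle-to-gomisin G ratio of 5.65 (95% exact counting interval 1.92 to 22.6), and did not pass the test (adjusted p = 0.130). The coactivator genes did not pass it either: YAP1 had a log2 change of -0.22 (SE 0.18, adjusted p = 0.521) and WWTR1 one of -0.36 (SE 0.23, adjusted p = 0.397). Against the vehicle mean, YAP1 lay at -0.43 in gomisin G replicate 1 and at -0.027 in replicate 2, so its size depended on replicate 1. WWTR1 lay at -0.38 and -0.32.

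The YAP/TAZ target list as a whole fell. Of its 24 genes 22 were tested, and 21 of these had a negative log2 change, with a median of -1.12 (adjusted p = 1.42e-12, and adjusted p = 0.386 with an estimated correlation). Of the 22, 8 fell when adjusted over all genes and 16 when adjusted over the list alone, and 0 rose by either count. Besides CCN1, AMOTL2 and CCN2, the called members included AJUBA, a LIM-domain adaptor that binds LATS kinases (log2 change -1.45), and CCDC80 (-2.04). The median was -1.24 in gomisin G replicate 1 and -0.88 in replicate 2. Components of the Hippo pathway itself also fell as a list of 27 tested genes, with a median of -0.35 (adjusted p = 2.73e-06, and adjusted p = 0.621 with an estimated correlation). The size of this fall depended on gomisin G replicate 1, with medians of -0.55 in replicate 1 and -0.19 in replicate 2. On the voom scale the median of -0.36 became -0.19 without gomisin G replicate 1, -0.55 without gomisin G replicate 2, -0.14 with the length trend removed and -0.16 with length and GC trends removed. Among them 9 genes fell adjusted over the list alone and 4 over all genes. These 4 were AMOTL2, the kinase gene LATS2 (from 73.3 to 31.8 CPM), and WWC2 (log2 change -1.67) and WWC1 (-0.94), which encode KIBRA-family scaffolds. AMOTL2, LATS2 and PTPN14 (log2 change -0.82) are tested members of both lists, so the 2 list results are not separate. WWC1 lost its call without either vehicle library, and LATS2 without vehicle replicate 2. In such fits the gomisin G pair alone supplies the spread. The log2 changes stayed similar, at -0.96 and -0.92 for WWC1 without vehicle replicates 1 and 2, and at -1.10 for LATS2 without vehicle replicate 2. WWC1 also missed the threshold with RLE factors (adjusted p = 0.0510), upper-quartile factors (0.0546) and the legacy fit (0.0512).

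**Figure D1:**
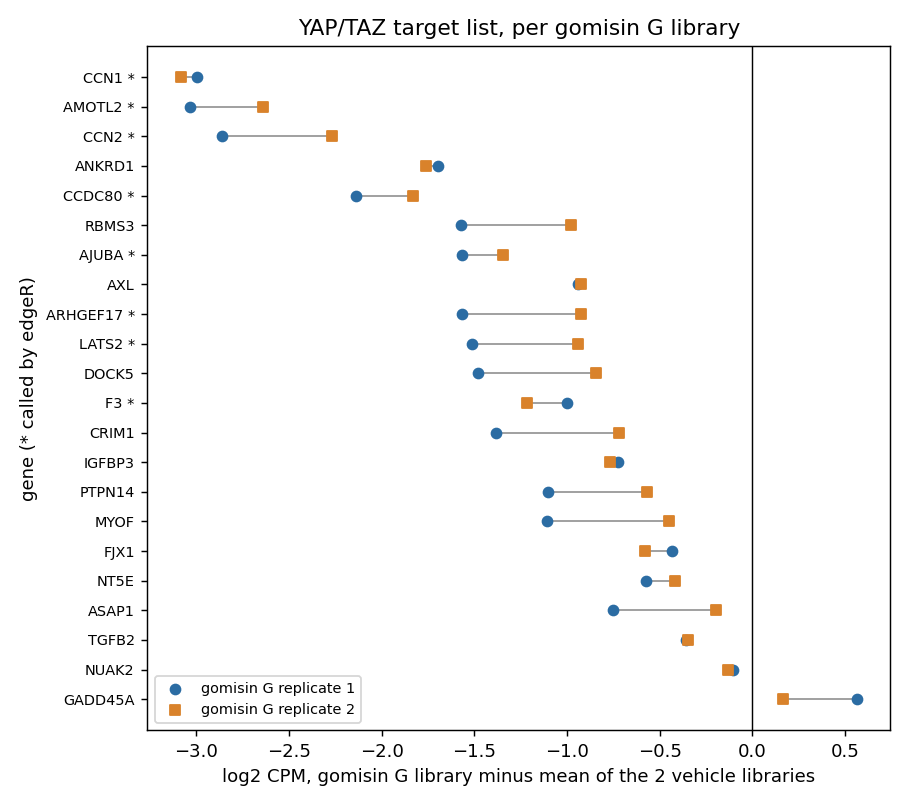
Log2 CPM of each gomisin G library minus the mean of both vehicle libraries (x axis) for the 22 tested genes of the YAP/TAZ target list (y axis, ordered by fitted log2 change). Circles are replicate 1 and squares replicate 2, a line joins both, and a star marks genes called by edgeR. CCN1 lies at -3.00 and -3.08, and GADD45A alone lies above 0 in both libraries.

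Over all tested genes, 287 were called, of which 145 rose and 142 fell. Of these, 126 rose and 111 fell by at least 1 on the log2 scale. In all 287 both gomisin G libraries lay beyond both vehicle libraries, as they did in 54.2% of tested genes, where chance gives 33.3%. An unadjusted p below 0.05 was found for 3232 genes. Fits without a vehicle library rest their spread on the gomisin G pair, which differed more than the vehicle pair. The count moved with single libraries. It was 160 without vehicle replicate 1, 135 without vehicle replicate 2, 2833 without gomisin G replicate 1 and 6322 without gomisin G replicate 2, the latter 2 fits resting their spread on the vehicle pair. DESeq2 called 818 genes, among them 280 of the 287.

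Among called protein-coding genes with a mean log2 CPM of at least 1, the largest increases included transcription factor genes. KLF2, a Krüppel-like factor (chromosome 19, 16324817 to 16327874), rose from 28.4 ± 0.980 to 277.5 ± 62.6 CPM, a log2 change of 3.29 (SE 0.21, adjusted p = 0.00147). JUN, the AP-1 subunit (chromosome 1, 58780788 to 58784327), rose from 42.9 ± 3.26 to 339.8 ± 7.80 CPM, a log2 change of 2.99 (SE 0.17, adjusted p = 0.00143). Further genes among the 10 largest such increases were the betaine and GABA transporter gene SLC6A12 (log2 change 3.29), the intestinal keratin gene KRT20 (2.61), CHI3L1 (2.57), CREB5 (2.42), the dystrobrevin gene DTNA (2.40), the tubulin gene TUBA1A (2.19) and LCN15 (2.15). SLC6A12 averaged 0.340 CPM in vehicle and 3.40 CPM with gomisin G. TUBA1A has close copies among the alpha-tubulin genes, so its value is uncertain. CREB5 missed the threshold with limma voom (adjusted p = 0.0514), and DTNA without vehicle replicate 2 (adjusted p = 0.0698). Without vehicle replicate 2 the log2 change of CHI3L1 was 3.17.

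Among called protein-coding genes with a mean log2 CPM of at least 1, the largest decreases, besides CCN1, AMOTL2 and CCN2, were HRNR (log2 change -3.10, SE 0.31), FLG (-3.06, SE 0.30), C4BPB (-2.89, SE 0.20), NDP (-2.81, SE 0.41), KLHDC7A (-2.63, SE 0.38), MAB21L4 (-2.43, SE 0.23) and CLIC5 (-2.35, SE 0.21). Without gomisin G replicate 2 the log2 change of KLHDC7A was -3.52. Below that level of expression ANO2, named after its value was seen, fell further (-4.33, SE 0.63, adjusted p = 0.0223). FLG and HRNR encode filaggrin and hornerin of the epidermal barrier and neighbour each other on chromosome 1, at 152302175 to 152325203 and 152212082 to 152224193. FLG fell from 8.28 ± 0.482 to 0.986 ± 0.124 CPM and HRNR from 8.28 ± 0.579 to 0.963 ± 0.201 CPM. Both overlap the antisense gene FLG-AS1, and with the strand setting unknown the counts of all 3 cannot be told apart. C4BPB, which encodes the beta chain of the complement regulator C4b-binding protein, fell from 149.0 ± 26.2 to 20.1 ± 2.77 CPM. NDP encodes norrin, a ligand of frizzled receptors, and CLIC5 a chloride intracellular channel protein.

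Genes of DNA replication and the G1/S transition fell as a list. All 36 members had a negative log2 change, with a median of -0.75 (adjusted p = 1.53e-21, and adjusted p = 0.349 with an estimated correlation). Of the 36, 12 fell over all genes and 32 adjusted over the list alone, and fry also called the list (adjusted p = 0.0324). The members with the lowest p were MCM10 (log2 change -1.26), the exonuclease gene EXO1 (-1.14), the replication licensing gene CDC6 (-0.93) and the helicase gene MCM6 (-0.89). Without vehicle replicate 1 the adjusted p was 0.206 for CDC6 and 0.265 for MCM6. Without vehicle replicate 2 it was 0.0983 for EXO1, 0.256 for CDC6 and 0.320 for MCM6. Genes of G2/M and mitosis fell as a list of 35, with a median of -0.34 (adjusted p = 9.2e-08, and adjusted p = 0.349 with an estimated correlation). Of these edgeR called 0 over all genes (17 had an unadjusted p below 0.05, DESeq2 called 9 and limma voom 0), and 13 fell adjusted over the list alone. The spindle checkpoint genes BUB1B and BUB1 had log2 changes of -0.78 (adjusted p = 0.0583) and -0.63 (adjusted p = 0.0765).

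The list of MYC targets and ribosome biogenesis genes fell with a median of -0.18 over 30 genes (adjusted p = 0.00104, and adjusted p = 0.608 with an estimated correlation). The median was -0.071 in gomisin G replicate 1 and -0.40 in replicate 2. On the voom scale it was -0.20, and -0.40 without gomisin G replicate 1, -0.070 without gomisin G replicate 2, -0.30 with the length trend removed and -0.31 with length and GC trends removed. Here edgeR called 0 members over all genes (9 had an unadjusted p below 0.05, DESeq2 called 4 and limma voom 0) and 3 fell adjusted over the list alone. NOLC1, a nucleolar phosphoprotein gene, had a log2 change of -0.70 (adjusted p = 0.0606). The list missed the threshold without vehicle replicate 1 (adjusted p = 0.0548) and without gomisin G replicate 2 (adjusted p = 0.0659). Replication-dependent histone genes, whose main transcripts lack poly(A) tails, rose as a list of 11 tested genes out of 47. Over the whole list, tested or not, counts summed to 644 and 522 in the vehicle libraries and 1199 and 931 in the gomisin G libraries. All 11 had a positive log2 change, with a median of 0.89 (adjusted p = 0.000708, and adjusted p = 0.386 with an estimated correlation). Of these edgeR called 0 over all genes (6 had an unadjusted p below 0.05, DESeq2 called 1 and limma voom 0), and 5 rose adjusted over the list alone. The linker histone gene H1-2 averaged 18.1 CPM in vehicle and 33.6 CPM with gomisin G (adjusted p = 0.113). Histone genes have close copies, so single values are uncertain, and without the expression filter the list missed the threshold (adjusted p = 0.0789), with a median of 0.37 against 0.86 on the voom scale. The list stayed called with the length trend removed (adjusted p = 0.0141, median 0.51) and with length and GC trends removed (adjusted p = 0.00505, median 0.48).

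Actin cytoskeleton genes and targets of the serum response factor SRF fell as a list of 23, with a median of -0.32 (adjusted p = 0.000898, and adjusted p = 0.386 with an estimated correlation). Of the 23, 5 fell and 1 rose over all genes, and 6 fell and 2 rose adjusted over the list alone. By fry the list had an adjusted p of 0.0190. The tropomyosin gene TPM1 fell from 223.4 ± 34.7 to 54.7 ± 0.310 CPM (log2 change -2.03), the calponin gene CNN2 had a log2 change of -0.97 and the caldesmon gene CALD1 one of -1.99. The other genes that fell were ACTG1 and FLNA, named after their values were seen. TGFB1I1, which encodes the focal adhesion adaptor HIC-5, rose by 1.10. The calls of CNN2 and TGFB1I1 were lost without vehicle replicate 1 (adjusted p = 0.262 and 0.206) and without vehicle replicate 2 (adjusted p = 0.214 and 0.117).

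Immediate early genes rose as a list of 30, with a median of 0.24 (adjusted p = 0.0308, and adjusted p = 0.386 with an estimated correlation). The rise was not general, as 18 of the 30 had a positive and 12 a negative log2 change. Of the 30 genes, 4 rose and 1 fell over all genes, and 9 rose and 2 fell adjusted over the list alone. JUN, JUND (log2 change 1.85), KLF6 (1.42) and ZFP36 (1.10), which encodes an mRNA decay factor, rose. DUSP6, a phosphatase gene of the ERK pathway named after its value was seen, fell. ZFP36 lost its call without vehicle replicate 1 (adjusted p = 0.134) or 2 (adjusted p = 0.187), and the list lost its own with the length trend removed (adjusted p = 0.0775) and with the length and GC trends removed (adjusted p = 0.177). Its median on the voom scale was 0.23, and 0.20 and 0.11 under these settings.

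Interferon response genes rose as a list of 30, of which 27 had a positive log2 change, with a median of 0.49 (adjusted p = 3.06e-06, and adjusted p = 0.386 with an estimated correlation). Of these 4 rose over all genes and 7 adjusted over the list alone. The exonuclease gene ISG20 had a log2 change of 1.29, the oligoadenylate synthetase family genes OASL and OAS1 had 0.98 and 1.21, and RSAD2, which encodes viperin, had 0.93. OASL averaged 132.9 ± 11.2 CPM in vehicle and 261.9 ± 23.2 CPM with gomisin G. Calls were lost without vehicle replicate 1 for OASL (adjusted p = 0.373), OAS1 (0.240) and RSAD2 (0.410), and without vehicle replicate 2 for ISG20 (0.147), OASL (0.220) and RSAD2 (0.187). RSAD2 also missed the threshold without the expression filter (adjusted p = 0.0507).

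The list named for pancreatic ductal epithelium, which also holds the intestinal keratin gene KRT20, rose over 24 tested genes. Its median was 0.40 (adjusted p = 0.00418, and adjusted p = 0.386 with an estimated correlation). On the voom scale the median was 0.45, and 0.25 without vehicle replicate 2 and 0.29 with at least 50 counts in 2 samples. Of the 24 genes, 2 rose over all genes, KRT20 and LGALS4, and 4 adjusted over the list alone. Those 2 calls do not show a rise of duct markers in particular. KRT20 rose from 2.62 ± 0.580 to 16.1 ± 2.01 CPM and the galectin gene LGALS4 from 2.14 ± 0.203 to 6.43 ± 0.876 CPM. The mucin gene MUC1 had a log2 change of 0.83 (adjusted p = 0.0862). LGALS4 missed the threshold with limma voom (adjusted p = 0.0533), without vehicle replicate 1 (0.164) and without vehicle replicate 2 (0.0970). Of 13 fibroblast markers 2 were tested, PDGFRB at 1.40 CPM in vehicle and 4.15 CPM with gomisin G (adjusted p = 0.0549) and COL1A1 at 3.37 and 5.98 CPM (adjusted p = 0.189). That pair was called as a list with a median of 1.198 (adjusted p = 0.0340, and adjusted p = 0.608 with an estimated correlation), with 0 genes called over all genes by edgeR, DESeq2 or limma voom, 2 with an unadjusted p below 0.05 and 2 rising adjusted over the list alone. It missed the threshold without gomisin G replicate 2 (adjusted p = 0.375) and without the expression filter (0.137, with a median of 0.73 against 1.17 on the voom scale).

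Lysosome and autophagy genes rose as a list of 34, with a median of 0.25 (adjusted p = 0.00103, and adjusted p = 0.386 with an estimated correlation), and edgeR called 0 members over all genes or adjusted over the list alone (11 had an unadjusted p below 0.05, DESeq2 called 2 and limma voom 0). CTSD, which encodes the protease cathepsin D, averaged 370.2 CPM in vehicle and 817.6 CPM with gomisin G (adjusted p = 0.0601). Targets of the oxidative stress factor NRF2 rose as a list of 26, with a median of 0.27 (adjusted p = 0.0296, and adjusted p = 0.386 with an estimated correlation), made up of 0.35 in gomisin G replicate 1 and 0.12 in replicate 2. On the voom scale it was 0.25, and 0.12 without gomisin G replicate 1 and 0.37 without gomisin G replicate 2. Of these 1 rose over all genes, and 7 rose and 3 fell adjusted over the list alone. The aldo-keto reductase gene AKR1C3 rose by 1.37, whereas FTL had a log2 change of 1.08 (adjusted p = 0.0786) and HMOX1 one of -0.70 (adjusted p = 0.0920). AKR1C3 has close copies and lost its call without vehicle replicate 1 (adjusted p = 0.155) or 2 (0.161). Fatty acid synthesis genes fell as a list of 16, with a median of -0.42 (adjusted p = 0.00361, and adjusted p = 0.664 with an estimated correlation), made up of -0.53 in gomisin G replicate 1 and -0.19 in replicate 2. On the voom scale it was -0.43, and -0.20 without gomisin G replicate 1. Of these edgeR called 0 over all genes (6 had an unadjusted p below 0.05, DESeq2 called 2 and limma voom 0), and 1 rose and 2 fell adjusted over the list alone. The desaturase genes FADS1 and SCD had log2 changes of -0.80 (adjusted p = 0.0891) and -0.72 (adjusted p = 0.105). With the length trend removed, both the NRF2 and the fatty acid lists missed the threshold (adjusted p = 0.0505 each) with voom medians of 0.24 and -0.34. With length and GC trends removed both were called (adjusted p = 0.0237 and 0.00903, medians 0.19 and -0.29). The NRF2 list also missed the threshold with at least 50 counts in 2 samples (adjusted p = 0.0896, median 0.12).

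Cytosolic ribosomal protein genes and nuclear genes of the respiratory chain were called as lists that rose, with medians that lay on opposite sides of 0 in the 2 gomisin G libraries. Ribosomal protein genes had a median log2 change of 0.24 over 42 genes (adjusted p = 0.00606, and adjusted p = 0.792 with an estimated correlation), made up of 0.50 in replicate 1 and -0.089 in replicate 2. Respiratory chain genes had a median of 0.22 over 36 genes (adjusted p = 0.0235, and adjusted p = 0.792 with an estimated correlation), made up of 0.47 in replicate 1 and -0.057 in replicate 2. In both lists 0 members were called by edgeR, DESeq2 or limma voom over all genes, or by edgeR adjusted over the list alone, and 0 and 2 members had an unadjusted p below 0.05. RPLP2 had a log2 change of 0.47 (adjusted p = 0.356) and COX6A1 one of 0.61 (adjusted p = 0.202). On the voom scale the medians were 0.21 for ribosomal protein genes and 0.20 for respiratory chain genes. Without gomisin G replicate 1 both lists turned to the negative side (medians -0.091 and -0.059, adjusted p = 0.0526 and 0.387), and without gomisin G replicate 2 the medians were 0.51 and 0.48. Both missed the threshold without vehicle replicate 2 (adjusted p = 0.239 and 0.285, with a median of 0.12 for the respiratory chain) and with the length trend removed (0.0650 and 0.216, medians 0.12 and 0.13). With length and GC trends removed the ribosomal protein list was called (adjusted p = 0.0304, median 0.16) and the respiratory chain list was not (adjusted p = 0.0648, median 0.14). Gomisin G replicate 1 stood apart from the other libraries by exon length. The Spearman correlation across genes of its log2 ratio to replicate 2 with exon length was -0.65, against -0.38 for the ratio of vehicle replicate 1 to replicate 2, and genes are not independent replicates.

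**Figure D2:**
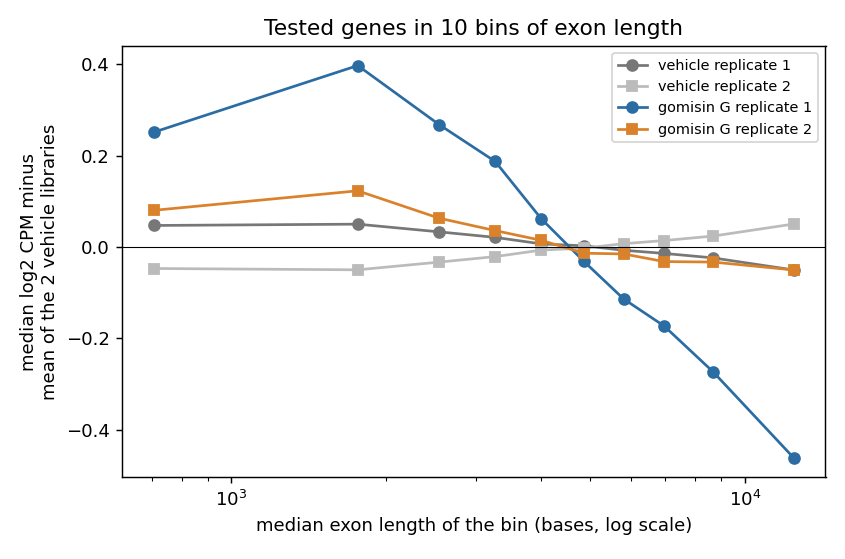
Median log2 CPM of each library minus the mean of both vehicle libraries (y axis) for tested genes in 10 bins of exon length (x axis, bases, log scale), with 1 line per library. Gomisin G replicate 1 runs from 0.40 in the bin at 1762 bases to -0.46 in the bin at 12440 bases, and gomisin G replicate 2 from 0.12 to -0.050 over the same bins.

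The remaining 16 lists were not called. Median log2 changes were 0.18 for NF-kB and cytokine genes, -0.14 for hypoxia genes (adjusted p = 0.270 each), -0.16 for p53 targets, 0.045 for tubulins, 0.21 for xenobiotic receptor targets, -0.052 for glycolysis, 0.24 for mitochondrially encoded genes and -0.066 for heat shock genes (adjusted p = 0.298 each). They were 0.42 for metallothioneins (adjusted p = 0.327), 0.073 for apoptosis regulators (0.340), -0.038 for cholesterol biosynthesis (0.514), -0.034 for endoplasmic reticulum chaperones (0.657), 0.10 for epithelial-mesenchymal transition (0.681), -0.046 for ATF4 and amino acid response (0.830) and -0.15 for the 2 tested immune and endothelial markers PECAM1 and CD14 (0.891). TGF-beta and SMAD targets had a median of -0.095 and a mean of 0.077 with an upward test direction (adjusted p = 0.514). With 1 library left out, 5 of these lists passed the threshold. Heat shock and glycolysis genes did so downward without gomisin G replicate 1 (adjusted p = 0.00424 and 0.0276) and hypoxia genes downward without vehicle replicate 2 (0.000309). Mitochondrially encoded genes and metallothioneins did so upward without gomisin G replicate 2 (0.00425 and 0.0288). Single members of these lists were called. The stress cytokine gene GDF15 rose from 347.0 ± 29.9 to 1090.9 ± 284 CPM and the amino acid transporter gene SLC7A5 fell from 570.8 ± 12.7 to 217.8 ± 23.8 CPM. The pro-apoptotic gene BIK rose from 33.3 to 94.1 CPM. On the log2 scale the pro-apoptotic gene BBC3 rose by 1.35, TP53I3 by 1.21, the SMAD-responsive genes ID3 and TSC22D1 by 1.70 and 1.37, the tight junction gene CLDN4 by 1.22 and the aldehyde dehydrogenase gene ALDH3A1 by 1.09. The glucose transporter gene SLC2A3 fell by 1.79 on the log2 scale. Without vehicle replicate 1 the calls of TP53I3 (adjusted p = 0.0534), ALDH3A1 (0.183), CLDN4 (0.170) and TSC22D1 (0.0673) were lost. Without vehicle replicate 2 those of TP53I3 (0.141), BBC3 (0.0950), GDF15 (0.0867), ALDH3A1 (0.249) and CLDN4 (0.151) were lost.

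**Figure D3:**
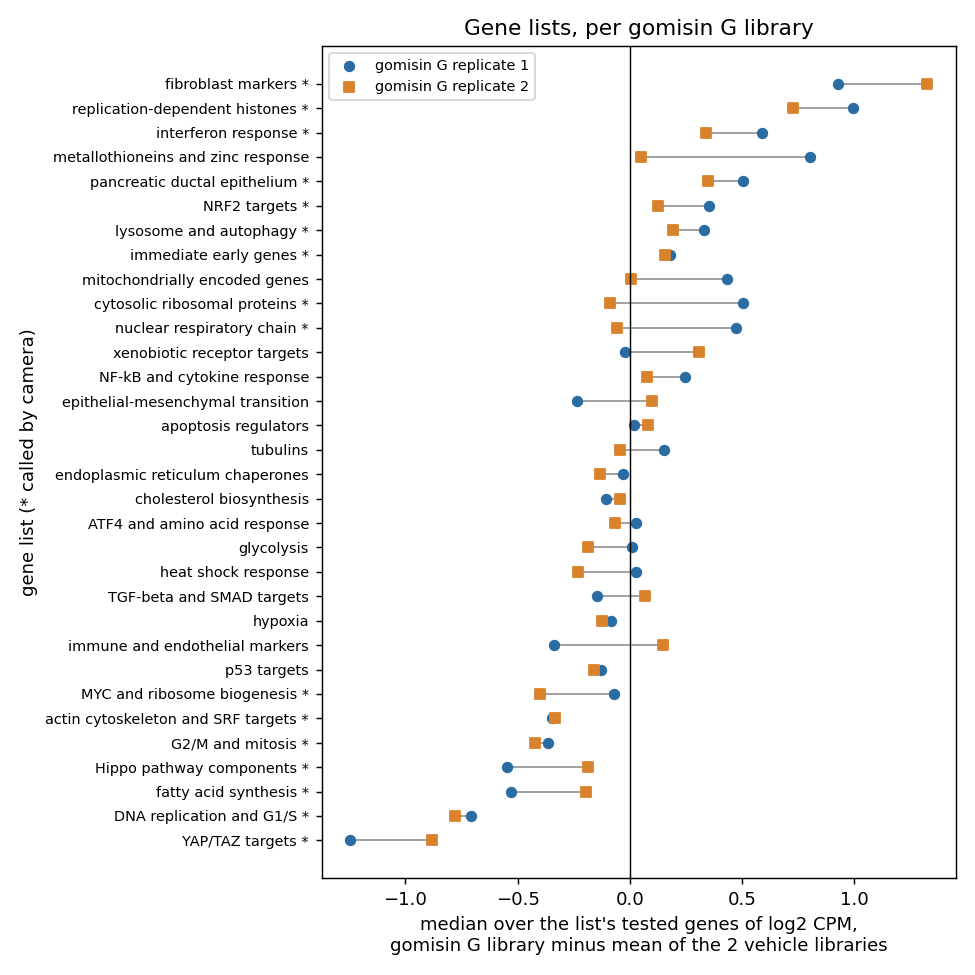
Median over each list's tested genes of log2 CPM of a gomisin G library minus the mean of both vehicle libraries (x axis) for the 32 gene lists (y axis, ordered by median fitted log2 change). Circles are replicate 1 and squares replicate 2, and a star marks the 16 lists called by camera. The DNA replication list lies at -0.71 and -0.78, whereas the ribosomal protein list lies at 0.50 and -0.089.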

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

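The removal of length and GC trends was chosen after seeing the data; the other settings were planned. The 287 calls (145 higher, 142 lower) stayed between 256 and 320 with other size factors, other filters, without mitochondrial and small structural RNA genes, with non-robust or legacy fits and with limma voom. They became 818 (387, 431) with DESeq2, 1075 (596, 479) with the length trend removed and 673 (327, 346) with length and GC trends removed, and the cause was not tested. Of the 287, 280, 280 and 268 remained called in the same direction. With 1 library left out the count ran from 135 to 6322, from 69 to 3025 higher and from 66 to 3297 lower. The fits without a gomisin G library leave the vehicle pair, which differed less, as the only replicates, and the lone sample is assumed to vary like them. Those without a vehicle library leave the gomisin G pair, which differed more, so a call lost there need not rest on that vehicle library. Named genes that lost a call there kept the sign of their log2 change. The labels do not say that the shared replicate numbers mark a batch. With the replicate block, which leaves fewer residual degrees of freedom, the count was 2885 (1408 higher, 1477 lower), with all 287 among them. Same-numbered libraries deviated together (correlation across genes 0.502, from 2 pairs). With the length trend removed this correlation was 0.37, so part of it went with that trend.

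The number of called lists, 16, was 0 with an estimated correlation and 2 with fry, and the YAP/TAZ list had adjusted p-values of 0.386 and 0.0767 there. With an estimated correlation the smallest unadjusted p over the 32 lists was 0.0181. That version rests on the 2 residual degrees of freedom, so it has little power to call a list here. The estimated correlations were not examined, so the reason for the loss was not tested. Under every other alternative the YAP/TAZ list was called, with adjusted p-values from 5.5e-11 to 1.97e-23. Camera's test direction, taken relative to all other genes, turned for 11 lists in some setting, as did the sign of 2 genes near no change, and the cause was not tested. List medians changed sign in 13 lists: 10 of these 11 (not p53 targets) and tubulins, xenobiotic receptor targets and epithelial-mesenchymal transition, whose test direction held. Leaving out vehicle replicate 1 turned ATF4 (adjusted p = 0.373), hypoxia (0.633), glycolysis (0.892) and immune and endothelial markers (0.955), and leaving out vehicle replicate 2 turned cholesterol biosynthesis (0.938). Leaving out gomisin G replicate 1 turned mitochondrially encoded genes (0.548), the respiratory chain (0.387), ribosomal proteins (0.0526) and immune and endothelial markers (0.989), and leaving out gomisin G replicate 2 turned p53 targets (0.936), ATF4 (0.503), endoplasmic reticulum chaperones and heat shock (0.842 each). Medians kept their sign there for p53 targets (-0.16 to -0.13) and endoplasmic reticulum chaperones (-0.031 to -0.030), and for mitochondrially encoded genes without gomisin G replicate 1. Over the 4 such fits the adjusted p ran from 0.140 to 0.955 for p53 targets, 0.246 to 0.938 for cholesterol biosynthesis, 0.371 to 0.651 for ATF4, 0.132 to 0.896 for endoplasmic reticulum chaperones, 0.00424 to 0.885 for heat shock, 0.000309 to 0.633 for hypoxia, 0.0276 to 0.892 for glycolysis, 0.00425 to 0.606 for mitochondrially encoded genes, 1.61e-08 to 0.387 for the respiratory chain, 1.46e-15 to 0.239 for ribosomal proteins and 0.660 to 0.989 for immune and endothelial markers. Others turned with the replicate block (ATF4, 0.943, with its median at -0.051 in both fits), with the length trend removed (mitochondrially encoded genes, 0.326) and with length and GC trends removed (endoplasmic reticulum chaperones, 0.984). PECAM1 had log2 changes of 1.15 and 0.34 without vehicle replicate 1 and gomisin G replicate 1, in a range from -1.36 to 1.15 over the 4 fits. CD14 had 0.0089 with upper-quartile factors, and 0.16 and 0.10 without vehicle replicate 2 and gomisin G replicate 2, in a range from -0.23 to 0.16. At this depth PECAM1, under 1 CPM in both groups, cannot be given a direction.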

Other observations

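Of the 287 called genes, 236 lay outside the 32 lists (124 higher, 112 lower). The genes in this paragraph were chosen after their values were seen. Among cell cycle genes, the cyclin gene CCND1 fell from a mean of 611.2 to 261.8 CPM (log2 change -1.22, SE 0.17), and the phosphatase gene CDC25A (-1.02), the ubiquitin ligase subunit gene SKP2 (-0.85) and the repressor genes E2F7 (-1.23) and E2F8 (-1.44) fell. The cyclin-dependent kinase inhibitor gene CDKN1C rose from 8.48 to 34.1 CPM (2.01, SE 0.25), and MXD4, a MAX dimerization partner, rose from 22.6 to 98.4 CPM (2.12, SE 0.17). The EGF receptor ligand genes AREG (1.51) and EREG (0.98) and the urokinase receptor gene PLAUR (1.21) rose. The epithelial transcription factor genes ELF3 (1.73) and CDX1 (2.57) rose, CDX1 from 0.508 to 3.06 CPM. All of these kept their sign under the alternatives, and E2F7, E2F8, CDKN1C, MXD4 and ELF3 were called under all 16. Without vehicle replicate 1, adjusted p-values were 0.0950 for CCND1, 0.241 for CDC25A, 0.316 for SKP2, 0.167 for EREG, 0.122 for PLAUR and 0.140 for CDX1. Without vehicle replicate 2 they were 0.0983 for CCND1, 0.0785 for CDC25A, 0.332 for SKP2, 0.434 for EREG, 0.0673 for PLAUR and 0.0513 for AREG. CDX1 was called under 11 of its 15 alternatives.

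In the 3 patterns that follow, all tests except that of FOXO markers were chosen after the result was seen, and the bounds of those on the response in replicate 1 and on histone length were changed after their values were seen. Bootstrap intervals resample the genes of a list, so they leave out the spread between libraries and treat related genes as independent. Gomisin G replicate 1 differed from replicate 2 by an SD of log2 ratios of 0.400, against 0.179 for the vehicle pair, over 8861 well-expressed genes. The gomisin G totals lay 1.40% apart and the vehicle totals 2.20%, which argues against depth. A smooth trend with exon length took up 42.7% of the variance of the log2 ratio, against 13.9% in the vehicle pair, so a length-dependent difference between libraries, such as in RNA integrity or library construction, may account for part of it. The SD left after removing the trend was 0.302, against 0.166 in the vehicle pair. A stronger response in replicate 1 cannot be told apart from this. With the trend removed the medians of 10 of the 16 called lists lay farther from 0 in replicate 1 (10 or fewer was the first bound against it, changed to 8). Those of the DNA replication list were -0.77 and -0.73. The lists were called from these same libraries, so this count cannot decide the question. Among the 10 were ribosomal proteins (0.36 in replicate 1 and -0.060 in replicate 2) and the respiratory chain (0.30 and -0.0089), which differed in sign.

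As lists, replication-dependent histone genes rose while DNA replication genes fell, with 0 of 11 and 12 of 36 tested genes called over all genes. By camera with an estimated correlation neither list was called (adjusted p = 0.386 and 0.349). The tested histone genes are short, with a median exon length of 1237 bases against 4423 for all tested genes, so the length trend is a candidate explanation. With it removed, the list's median went from 0.864 to 0.514 on the voom scale (95% bootstrap interval over genes of edgeR changes 0.268 to 0.823, adjusted p = 0.0141). This argues against the trend as the whole cause only as far as it holds below the mean log2 CPM of 4 above which it was fitted. Most tested histone genes lay below that level, among them H2AC6, H2BC11 and H2BC18, at 2.96, 0.89 and -0.44. H1-2 lay above it, at 4.70. Of the 644 and 522 listed histone counts in the vehicle libraries, H1-2 held 296 and 234. Of the 1199 and 931 in the gomisin G libraries it held 597 and 411. The argument therefore rests mostly on the trend extended to lower expression than it was fitted on. Over all listed histone genes, tested or not, the summed counts scaled to library totals were 1.78 times as high with gomisin G (95% exact counting interval 1.66 to 1.91; without H1-2, the gene with most counts, 1.72), which argues against counting noise. An effect of gomisin G on histone transcripts or on their polyadenylated forms stays open and was not tested, as does an uneven carry-over of RNAs without poly(A) tails, since nuclear ribosomal RNA, 7SK and 7SL genes also had a higher share with gomisin G (0.0188 and 0.0246% of counts against 0.0131 and 0.00905% in vehicle).

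KLF2 and JUN rose while the YAP/TAZ and SRF target lists fell. Of their tested genes, 8 of 22 and 5 of 23 fell over all genes, and 0 and 1 rose. By camera with an estimated correlation both lists had an adjusted p of 0.386. With the length trend removed, the smaller log2 change of KLF2 and JUN was still 2.95 (larger adjusted p = 0.000142), which argues against that trend for these 2 genes. Depletion of mevalonate products, as with statins, is expected to raise cholesterol biosynthesis genes. Their median was -0.038 (95% bootstrap interval over genes -0.19 to 0.073), below the assumed bound of 0.3. It was -0.11 in gomisin G replicate 1 and -0.045 in replicate 2. FOXO activation is a candidate explanation. The 18 tested genes listed as FOXO markers before their values were seen, without genes whose rise had already been seen, had a median of 0.59. Its bootstrap interval over genes was 0.029 to 0.766 (camera p = 0.000418, and p = 0.227 with an estimated correlation). By fry the list had an unadjusted p of 0.0786. In gomisin G replicates 1 and 2 the medians of these 18 genes were 0.42 and 0.68. CCND2, listed in error since FOXO factors repress it, is among them, and the other 17 had a median of 0.69 (interval 0.018 to 0.77). Of the 18 edgeR called 0 over all genes (8 had an unadjusted p below 0.05, and DESeq2 called 3) and 8 adjusted over the list alone, TXNIP had 0.73 and IRS2 -0.43, and several also follow slower growth, so FOXO activity may not be the reason.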
